A study of Mus musculus with 6 samples.

How the data were processed

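Regulatory T cells (Treg cells) from the spleen of mice labelled wild-type (WT) and of mice labelled MAZR-cKO, in which Cre recombinase under Cd4 control is meant to delete the gene for the transcription factor MAZR, were profiled by RNA-seq in 6 libraries, 3 per label. Both genotypes carried the DEREG transgene, whose green fluorescent protein reports Foxp3 expression, and per the labels' protocols CD4-positive, eGFP-positive cells were sorted, about 800000 to 2000000 per RNA preparation. The mice were 6 to 8 weeks old and of the C57BL/6 strain. Per the labels' protocols, RNA was extracted with an RNeasy kit and libraries were prepared with a stranded, poly(A)-selecting TruSeq kit. The labels do not say whether each library came from 1 animal or from a pool, so the p-values measure the spread between these libraries. Sex-linked transcripts, given below, argue against 1 animal as the source of each library except MAZR-cKO 2.

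The authors deposited 1 table of gene-level values for all 6 libraries, with 46078 Ensembl gene identifiers and no value column outside these libraries. FastQC, STAR 2.5.2b, Subread 1.5.1, R 3.4 and edgeR, with the mouse build mm10, are named in the submitters' processing notes, which give no roles, settings, strand mode or annotation release. The unit is CPM, reads scaled to a common library total, as read from the deposited values. Each column sums to 96.2 to 99.2% of the nominal total of the unit, as with library sizes rescaled by a normalization factor. Within each library every value above 0 was a whole multiple of the smallest one, within a tolerance of 0.01 reads, for 100% of such values. Whole reads were therefore recovered for each gene. The recovered totals were 19148883, 18069527 and 17671951 reads in WT replicates 1, 2 and 3, and 15481565, 18369224 and 28184456 in the libraries labelled MAZR-cKO 1, 2 and 3, so that 1 read was worth 0.0347 to 0.0621 CPM. All 6 libraries covered abundant genes well, while a gene at 1 CPM rested on about 16 to 29 reads.

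Identifiers were matched without version numbers to the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes, and 45143 of them were found there. No symbol was given for 22037 identifiers, of which 21301 were named from the annotation. A further 345 had several symbols and 12 symbols had been turned into dates, so symbols were taken from the annotation by identifier. Coordinates are those of the annotation. No read positions were used, so exons, transcript variants and deleted segments could not be seen. Genes with near-identical copies (globins, heat shock and ribosomal protein genes, Ly6 genes and the enolase pseudogenes) or overlapping models are uncertain to the extent that reads were split between them. The 6 libraries were compared pairwise by a chi-square statistic of their reads over genes with 20 or more reads. It was 5.39 to 19.0 per degree of freedom, so none of the 6 was a copy of another.

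The comparison was fitted with limma 3.58.1 (R 4.3.3) on log2(CPM + 0.5), with an intensity trend, over the 12040 genes that reached 1 CPM in at least 3 libraries. Fold changes are therefore on the log2(CPM + 0.5) scale, which understates those of low genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Because the values were CPM, the count test was an alternative. edgeR 4.0.16 quasi-likelihood on the recovered reads tested 12957 genes and called 5. DESeq2 1.42.0 was added after seeing the data. Values are given as mean ± SD over 3 libraries. Single values were compared by an exact two-sided permutation test, which cannot go below p = 0.1 with 3 libraries against 3. Ratios for genes with 3 or fewer WT reads carry an exact (Clopper-Pearson) 95% interval, which covers counting error only.

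Replicate numbers 1 to 3 occur in the titles of both genotypes, and the descriptions give the libraries of a number a shared code whose meaning is not stated. After subtracting the genotype means, libraries with the same number correlated across genes at 0.40, 0.38 and 0.38. As each of the 3 was over 0.1, a limit fixed before the data were examined, the numbers were taken to pair the libraries. The fit without the block had been chosen beforehand and stays the one reported first, and values with the replicate number as a block are given where they differ in a call or by more than 1.5 times in a count.

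Of 34 gene lists fixed before the data were examined, 33 had 3 or more tested genes and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. They cover CD4 and CD8 lineage genes, Treg and other T cell programmes, signalling, stress, metabolism, ribosomal proteins, the MAZR family, mitochondrial transcripts, sex-linked transcripts, and markers of other cell types that a CD4-positive, eGFP-positive sort could hold. The list of stromal and endothelial markers, with 2 tested genes, was left out. camera with an estimated correlation and fry were alternatives. The genes to be named were also set beforehand: Patz1, which encodes MAZR, 17 key genes of the cell type and lineage, of which 16 are given here, and up to 4 genes of smallest p per list. To these came up to 12 called genes of largest fold change per direction whose libraries did not overlap between genotypes and whose higher mean was at least 1 CPM, leaving out predicted models and pseudogenes. The rule adds the 10 genes of smallest p only if fewer than 5 are called. Although 5 were called, 4 met the conditions, and the 10 of smallest p outside predicted models and pseudogenes were named too, a departure made after the count was seen. The same rule was applied to the fit with the block, and any other gene named was chosen after its values were seen.

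Other settings tried were pseudocounts of 0.1 and 1, no filter, a filter at 5 CPM, quantile normalization, equal medians, robust variance moderation, library weights, stricter thresholds and leaving out each library. In a first run the filter was reapplied to the libraries left, which removed Gh whenever a library labelled MAZR-cKO was left out. Values without single libraries or pairs are therefore for the genes tested with all 6, a choice made after that run, and those with the filter reapplied are given in the closing section. Added after seeing the data were DESeq2, the summed CPM of 4 Y-linked genes as a covariate, leaving out X and Y genes, and the same settings for the fit with the block. The matches of Gm33707 were found with BLAST 2.17.0 against the GENCODE transcripts. Read totals, summaries and plots were made in Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The fits were tested on simulated data: counts were drawn for the real genes at the real depths, with 50 genes changed by each of 1.3, 1.5, 2 and 4-fold. Recovery without the block depended on the spread between pairs that was simulated. With a log2 SD of 0.0397, estimated from the median gene of the real pairs, limma for this comparison, over 12063 genes, recovered 28, 41, 48 and 50 of them with 7 unchanged genes called. With the block it recovered 29, 41, 48 and 50 with 11 unchanged genes called. With an assumed SD of 0.15, the setting of the first test run, limma over 12068 genes recovered 0, 22, 43 and 50 without the block, with 1 unchanged gene called, and 37, 40, 48 and 50 with it, with 22 unchanged genes called. The share of unchanged genes among the calls with the block was thus above the nominal 5%. With no gene changed, 0 or 1 were called. camera called a list of 30 genes changed by 1.3-fold and did not call an unchanged list of 30 genes. The simulated genes were drawn independently, so this does not test camera on lists whose genes vary together.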

Results

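Gene expression was measured by RNA-seq in splenic Treg cells of mice labelled WT and MAZR-cKO, with 3 libraries under each label. Treg cells are the CD4-positive T cells that restrain immune responses and depend on the transcription factor Foxp3. MAZR, encoded by Patz1, is a zinc finger transcription factor with a known role in the choice between the CD4 and CD8 lineages in the thymus. The table held 15481565 to 28184456 reads per library, and 17865 to 18785 genes had at least 1 read. The comparison asked which genes differ between the libraries of the 2 labels, of which MAZR-cKO is meant to mark the deletion of MAZR in T cells.

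Patz1 was the first check of the labels, and it was higher, not lower, in the libraries labelled MAZR-cKO. It lies on chromosome 11 from 3288874 to 3309083 (mm10, plus strand) and is annotated as protein-coding. Its level was 71.6, 74.9 and 67.6 CPM in WT replicates 1, 2 and 3, and 177, 181 and 179 CPM in the libraries labelled MAZR-cKO 1, 2 and 3. The means were 71.4 ± 3.6 and 179 ± 2.1 CPM (SD, n = 3), a 2.51-fold difference with no overlap between the genotypes. On the log2 scale the difference was 1.32 (SE 0.05), with a limma adjusted p of 3.7e-06, while the exact permutation test gave p = 0.1, the smallest it allows. A gene-level value sums all exons of Patz1, so it does not show whether the part meant to be deleted was present. The labels are therefore written as labels throughout, and each direction given here is that of the libraries labelled MAZR-cKO against those labelled WT. A lowly read model on the same strand, Gm11944 (3.31 CPM on average), and one on the opposite strand, Gm12592 (0.778 CPM), overlap Patz1 and are far below the difference of the gene.

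Besides Patz1, 4 genes differed between the genotypes, all higher in the libraries labelled MAZR-cKO: Gh, Gm33707, Nod1 and Cacna1g. Gh, which encodes growth hormone, had 1 read in each WT library and 842 to 1225 reads in each library labelled MAZR-cKO, or 0.0539 ± 0.0027 against 46.8 ± 5.6 CPM (SD, n = 3). Its ratio was 853, with a 95% counting interval of 292 to 4140. Gm33707, a processed pseudogene, had 2 reads in the WT libraries together and 251 to 508 in each of the others, at 17.4 ± 1.7 CPM, a ratio of 488 with an interval of 135 to 4034. Nod1, an intracellular sensor of bacterial peptidoglycan, rose from 132 ± 4.5 to 189 ± 8.2 CPM, and Cacna1g, a subunit of a T-type calcium channel, rose from 0.438 ± 0.234 to 4.12 ± 0.64 CPM.

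**Figure D1:**
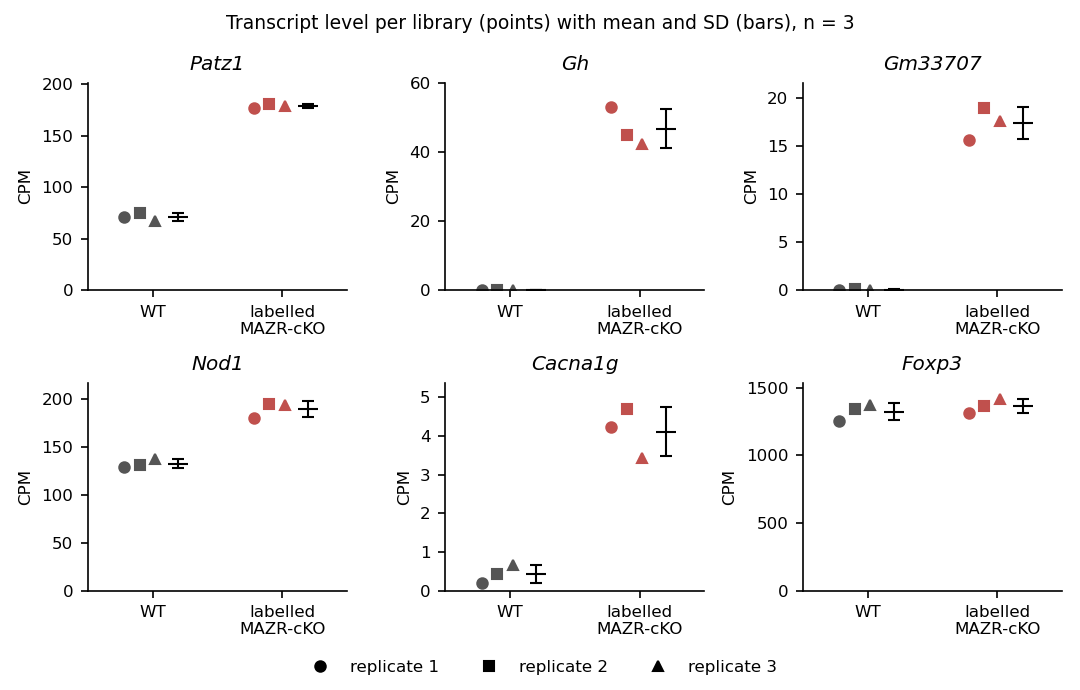
CPM (vertical axes, linear, from 0) of 6 genes in each library, with WT in grey and the libraries labelled MAZR-cKO in red, point shape for the replicate number, and bars for mean and SD (n = 3). Patz1, Gh, Gm33707, Nod1 and Cacna1g do not overlap between the genotypes, while Foxp3 lies at 1323 CPM in WT and 1364 CPM in the libraries labelled MAZR-cKO on average.

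The log2 fold changes in limma were 6.41 for Gh (SE 0.14, adjusted p = 8.4e-08), 5.06 for Gm33707 (SE 0.17, adjusted p = 1.8e-06), 0.51 for Nod1 (SE 0.05, adjusted p = 0.0096) and 2.32 for Cacna1g (SE 0.23, adjusted p = 0.010). Of 12040 genes tested these 5, Patz1 included, were called and none was lower. At an unadjusted p under 0.05 there were 280 higher and 352 lower genes, 632 in all where chance alone gives 602. With the replicate number as a block there were 479 higher and 802 lower, 1281 in all. edgeR called the same 5 genes of 12957, with 0 lower, and had 394 higher and 279 lower at an unadjusted p under 0.05. With the block, edgeR had 623 higher and 655 lower at that limit, so the excess of lower genes in limma depended on the method. Gh spans chromosome 11 from 106300271 to 106301865 and Cacna1g 94408391 to 94474198 of the same chromosome. Nod1 lies on chromosome 6 from 54923949 to 54972612, and Gm33707 on chromosome 3 from 60769887 to 60770455. Gm33707 was 89.5% identical over 573 aligned positions to Eno1, the glycolytic enzyme gene, which stood at 125 ± 2.6 CPM in WT and 113 ± 4.0 CPM in the libraries labelled MAZR-cKO. Of the 10 genes with the smallest p, leaving out the pseudogene Gm33707, Wnt3, Xkrx, Brsk1, Cd177, Prrt1 and Col27a1 did not pass, with limma adjusted p of 0.060 to 0.076. Leaving out library MAZR-cKO 3 gave 14 calls, of which 13 were higher and 1 lower, or 10 with the filter reapplied. Nod1 missed the threshold in limma without WT 1 or WT 2 (adjusted p = 0.069 and 0.062), and Cacna1g without WT 2, MAZR-cKO 1 or MAZR-cKO 2 (0.062, 0.086 and 0.055). Both missed it with the summed CPM of Y-linked genes as a covariate (limma adjusted p = 0.054 and 0.099). Over all alternatives the limma adjusted p of these genes ran up to 0.069 and 0.099.

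With the replicate number as a block, limma called 46 genes, of which 36 were higher and 10 lower in the libraries labelled MAZR-cKO, and all 5 genes above were among them. Wnt3, a secreted Wnt ligand, stood at 8.75 ± 0.71 CPM in WT and 15.4 ± 0.62 CPM in the libraries labelled MAZR-cKO, and Smo, the transducer of Hedgehog signals, at 2.93 ± 0.50 and 6.20 ± 0.70 CPM. Cd177, a glycoprotein best known from neutrophils, went from 0.805 ± 0.080 to 3.99 ± 1.5 CPM, and Clcf1, a cytokine of the interleukin-6 family, from 134 ± 4.4 to 175 ± 11 CPM. The collagen gene Col27a1 went from 10.3 ± 1.7 to 23.2 ± 4.2 CPM, Prrt1 from 13.0 ± 3.1 to 27.8 ± 1.1 CPM and the aldehyde dehydrogenase gene Aldh2 from 27.1 ± 3.6 to 41.0 ± 6.1 CPM. Brsk1, Ppic, Spaca6, Rhod and As3mt, the other genes of largest increase, had means of 0.428 to 6.70 CPM in WT and of 2.14 to 12.4 CPM in the libraries labelled MAZR-cKO. With the block, Smo, Ppic, Spaca6, Rhod and As3mt lost their call with no filter. Smo, Ppic, Spaca6 and Rhod lost it with DESeq2, As3mt, Ppic and Rhod with quantile normalization, and As3mt and Rhod with equal medians. The other genes named in this paragraph kept their call in these settings, but all of the named genes lost it without replicate 1.

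Among the 10 lower genes, Gpr83, a receptor characteristic of Treg cells, fell by 0.53 on the log2 scale (SE 0.09, limma adjusted p = 0.031 with the block), from 270 ± 35 to 194 ± 63 CPM. The constitutive chaperone gene Hspa8 fell by 0.65 (adjusted p = 0.038 in the same limma fit), from 222 ± 61 to 145 ± 59 CPM, and Vim, which encodes the filament protein vimentin, went from 760 ± 81 to 643 ± 88 CPM. Ctsw, which encodes cathepsin W, went from 71.7 ± 6.2 to 53.3 ± 11 CPM. These overlapped between the genotypes and were lower within each of the 3 pairs. With the block, all 4 lost their call with quantile normalization and with equal medians, Hspa8 and Vim in edgeR, and Gpr83 and Hspa8 with DESeq2 and with robust moderation. Fsd1l, Syp, Zcchc18 and Crmp1 were the lower genes without overlap, with log2 fold changes of -0.85 to -0.34. With the block, all 4 of these also lost their call with quantile normalization, with equal medians and with DESeq2, and Crmp1 in edgeR. Syp and Zcchc18 lie on the X chromosome. The beta-globin gene Hbb-bs, a red cell transcript, was lower as well, at 15.1 ± 8.6 against 7.12 ± 2.5 CPM.

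**Figure D2:**
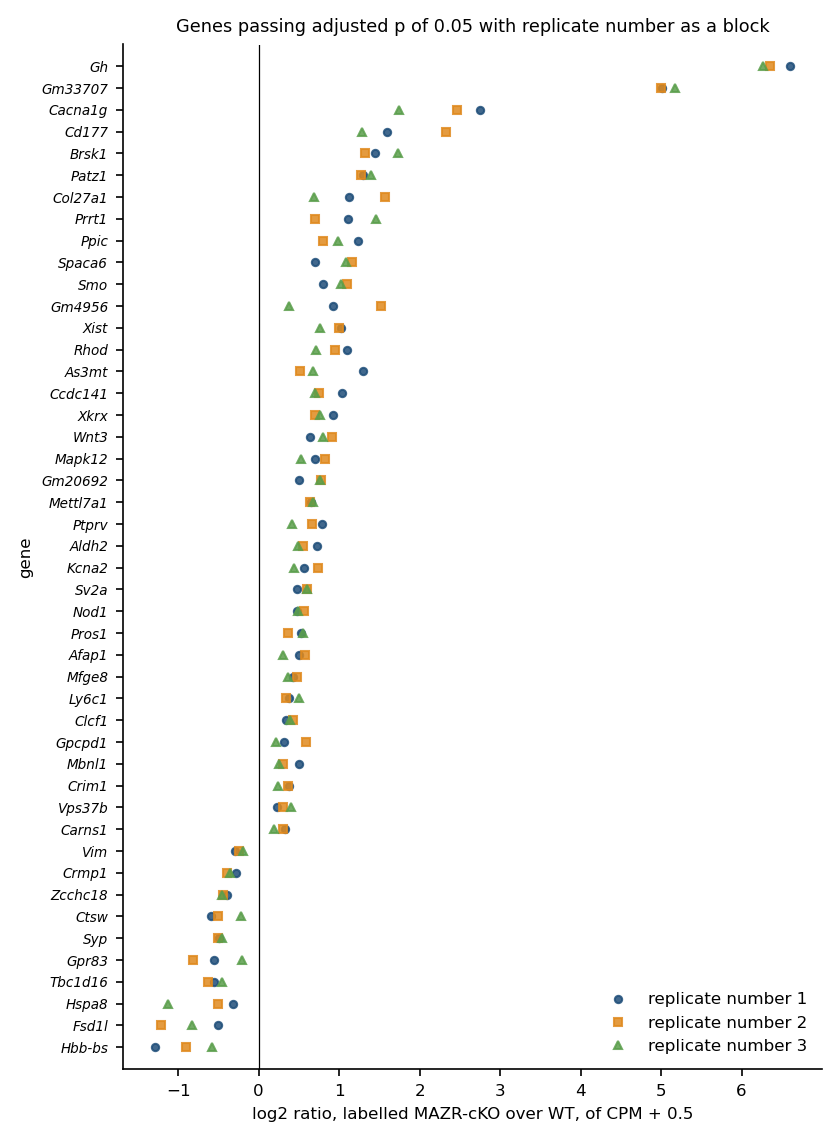
Log2 ratio (horizontal axis) of CPM + 0.5 between the libraries labelled MAZR-cKO and WT of the same replicate number, for each of the 46 genes (vertical axis) called by limma with the block; colour and shape mark the replicate number. All 46 genes have the same sign in the 3 pairs, which their selection by this fit favours, from Gh at the top to Hbb-bs at the bottom.

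All 46 genes had the same direction in the 3 pairs, which their selection by a fit on these pairs favours and which is no separate support. edgeR with the block called 43 of them among its own 46. Of the 46, 39 did not overlap between the genotypes, which the selection favours too. Of all tested genes, 5% were higher without overlap and 5.74% lower without overlap. Of the 36 higher genes, 15 had a WT mean under 10 CPM. The split into higher and lower genes was 22 to 1 with quantile normalization and 23 to 2 with equal medians. Without replicate 1 only 8 genes were called, all higher, and without replicate 3 there were 279, of which 145 were higher and 134 lower (5 and 311 with the filter reapplied). With the Y-linked covariate 15 were higher and 17 lower, 5 of them among the 46. These were Gh, Gm33707, Patz1, Prrt1 and Hspa8, while Nod1, Cacna1g and Xist lost their call. The covariate leaves fewer residual degrees of freedom than the 2 of the block alone.

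None of the key genes of Treg cells and of the CD4 and CD8 lineages was called by limma. Foxp3 stood at 1323 ± 63 CPM in WT and 1364 ± 51 CPM in the libraries labelled MAZR-cKO (SD, n = 3), a log2 difference of 0.05 (SE 0.06). Cd4 was at 907 ± 7.0 and 979 ± 39 CPM, and Cd8a, which MAZR is known to repress in earlier stages of T cell development, at 1.55 ± 0.19 and 1.72 ± 0.11 CPM, with Cd8b1 at 12.9 ± 1.1 and 14.2 ± 1.2 CPM. Zbtb7b, which encodes the CD4 lineage factor ThPOK, was at 387 ± 30 and 395 ± 23 CPM, and Runx3, a factor of the CD8 lineage, at 80.1 ± 6.0 and 72.2 ± 5.6 CPM. Runx1 was at 133 ± 3.0 and 141 ± 12 CPM.

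The interleukin-2 receptor gene Il2ra had 926 ± 156 CPM in WT and 853 ± 185 CPM in the libraries labelled MAZR-cKO. Ctla4 had 428 ± 38 and 424 ± 35 CPM, Ikzf2 869 ± 45 and 842 ± 69 CPM, Tnfrsf18 304 ± 21 and 292 ± 20 CPM, and Nrp1 400 ± 24 and 365 ± 33 CPM. Among genes of the naive and activated states, Ccr7 stood at 253 ± 9.9 and 250 ± 38 CPM and Cd44 at 160 ± 3.6 and 157 ± 13 CPM. Icos was at 324 ± 23 and 294 ± 23 CPM, and Klrg1 at 74.1 ± 9.0 and 71.4 ± 17 CPM. Across the 16 key genes given the log2 fold changes ran from -0.15 to 0.13. limma called 0 of the 16, 0 had an unadjusted p under 0.05, and edgeR and DESeq2 called 0 each. With the block 0 were called in limma, and 5 had an unadjusted p under 0.05, Icos, Nrp1, Il2ra and Runx3 lower and Cd4 higher, beside 1281 of all 12040 genes.

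Among the gene lists, 6 of 33 were called by limma's camera at the preset correlation, all lower in the libraries labelled MAZR-cKO by small amounts, and 0 with an estimated correlation, where camera's adjusted p was 0.862 for each of the 6. Of the Treg core list, 20 of 22 members were lower, with a median log2 fold change of -0.14 (camera adjusted p = 0.0042, or 0.862 with an estimated correlation). Its members of smallest p were Entpd1, Gpr83, Capg and Ikzf4. Entpd1, an ectonucleotidase, stood at 58.3 ± 2.5 CPM in WT and 51.2 ± 4.0 CPM in the libraries labelled MAZR-cKO, Capg at 341 ± 25 and 299.9 ± 26 CPM and Ikzf4 at 246 ± 10.4 and 227 ± 16 CPM. Of the cell cycle list, 37 of 38 members were lower, with a median of -0.14 (camera adjusted p = 0.0042). Mcm6, a subunit of the replicative helicase, was at 169.7 ± 15 and 152 ± 14 CPM, Tyms at 17.1 ± 3.8 and 13.6 ± 2.3 CPM, Uhrf1 at 40.5 ± 12 and 31.0 ± 5.5 CPM and Birc5 at 16.2 ± 4.7 and 12.1 ± 2.6 CPM. Ribosomal protein genes were lower in 60 of 75 (median -0.10, camera adjusted p = 0.00081) and oxidative phosphorylation genes in 37 of 42 (median -0.07, camera adjusted p = 0.0039). Heat shock genes were lower in 10 of 12 (median -0.11, camera adjusted p = 0.018) and genes of MHC class I presentation in 15 of 18 (median -0.07, camera adjusted p = 0.027).

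In these 6 lists 0 members were called over all genes without the block. Adjusted over the list alone, only Hsph1 and Hspa4l of the heat shock list passed, at 75.3 ± 6.2 and 62.7 ± 2.1 CPM and at 36.4 ± 1.5 and 31.0 ± 1.1 CPM. With the block Gpr83 and Hspa8 were the members called over all genes, while adjusted over the list alone 14 Treg core genes, 8 cell cycle genes, 5 heat shock genes and 1 MHC class I gene were lower. None was higher, and the ribosomal protein and oxidative phosphorylation lists had 0 in either direction. The block added a 7th list, immediate early and NF-kB response genes, with 22 of 30 members higher (median 0.06, camera adjusted p = 0.0036 with the block, 0.687 with the block and an estimated correlation), Nfkbia for example at 398 ± 21 and 445 ± 54 CPM.

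**Figure D3:**
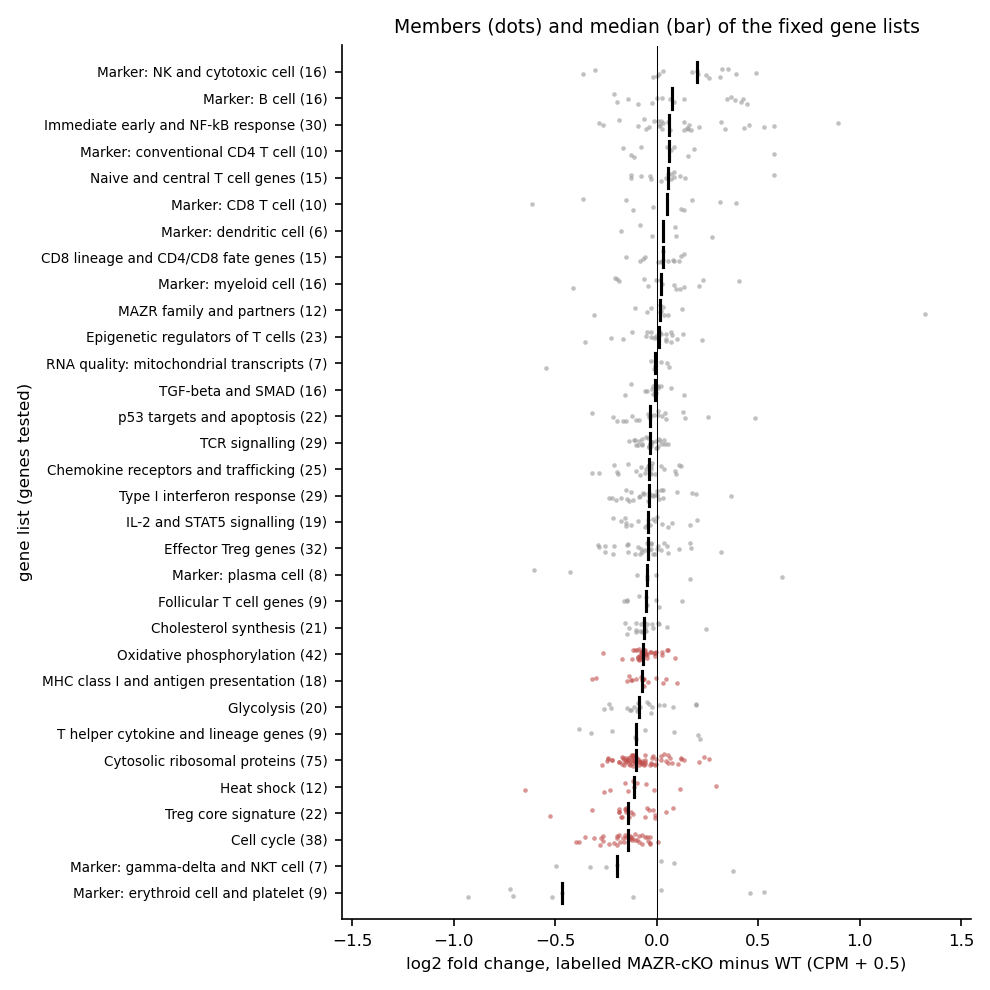
Log2 fold change (horizontal axis, log2 of CPM + 0.5, libraries labelled MAZR-cKO minus WT) of each tested member (dots) and median (black bars) of 32 gene lists (vertical axis, number of tested genes in brackets), leaving out the sex-linked list, with lists called by camera in red. The medians of the red lists lie between -0.14 and -0.07, and none was called with an estimated correlation.

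The calls of the lists rested on few libraries. Without library MAZR-cKO 2 none of the 6 passed, with camera adjusted p of 0.366 for Treg core, 0.526 for cell cycle, 0.148 for heat shock, 0.207 for oxidative phosphorylation, 0.737 for ribosomal proteins and 0.351 for MHC class I. Each list also missed the threshold without at least 1 other library. This held for Treg core without WT 3 (camera adjusted p = 0.145) and for cell cycle without WT 1 or MAZR-cKO 3 (0.475, with the direction turned, and 0.302). It held for heat shock without WT 3 or MAZR-cKO 3 (0.0635 and 0.389), oxidative phosphorylation without MAZR-cKO 1 (0.0668), ribosomal proteins without WT 1 (0.0727) and MHC class I without WT 2 or WT 3 (0.0705 and 0.196). With the summed Y-linked CPM as a covariate, Treg core and ribosomal protein genes were called higher (camera adjusted p = 0.0295 and 0.0011) and the other 4 lists were not called. Over all alternatives the adjusted p of Treg core ran from 1.7e-07 to 0.922.

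The libraries differed in sex-linked transcripts along the same line. Xist, which is transcribed from the inactive X chromosome of females, stood at 561, 774 and 355 CPM in WT replicates 1, 2 and 3 and at 1145, 1552 and 605 CPM in the libraries labelled MAZR-cKO 1, 2 and 3. It was called with the block (log2 fold change 0.93, limma adjusted p = 1.0e-05) and not without it. The summed level of 4 Y-linked genes, Ddx3y, Eif2s3y, Kdm5d and Uty, was 217, 164 and 276 CPM in WT and 116, 0.48 and 199 CPM in the libraries labelled MAZR-cKO. Library MAZR-cKO 2 thus held almost no Y-linked transcripts, and in each pair the library labelled MAZR-cKO had more Xist and less of the Y-linked sum. The other libraries held both Xist, at 355 to 1145 CPM, and Y-linked transcripts, at a sum of 116 to 276 CPM. This argues against a single animal as the source of each of them.

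Lists of naive T cell, effector Treg, T helper, follicular, interferon, p53, interleukin-2, T cell receptor, chemokine receptor, TGF-beta, glycolysis, cholesterol, epigenetic, lineage and MAZR family genes were not called, nor were the immediate early, sex-linked and mitochondrial lists. The adjusted p of all 27 lists not called by camera ran from 0.0572 to 0.974. In the effector Treg list 22 of 32 genes were lower (median -0.04), with Ebi3 at 23.2 ± 0.84 and 18.9 ± 1.8 CPM, Itgb1 at 527 ± 38 and 456 ± 41 CPM and Tigit at 121 ± 14 and 104 ± 8.8 CPM. Adjusted over the list alone, 0 passed without the block and 6, all lower, with it. In the T helper list 2 genes passed when adjusted over the list alone, Ahr at 27.5 ± 0.34 and 23.5 ± 0.75 CPM and Il18r1 at 143 ± 26 and 109 ± 6.7 CPM, both lower. In the naive T cell list Dapl1 alone did, at 5.21 ± 0.79 and 7.98 ± 0.25 CPM, beside Lef1 at 277 ± 12 and 254 ± 4.2 CPM. Patz1 was the only called member of the MAZR family list.

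None of the 9 marker lists of other cell types was called by camera (adjusted p 0.146 to 0.974). Adjusted over the list alone, 1 marker of conventional CD4 T cells (Dapl1) and 1 of gamma-delta and NKT cells passed. With the block, 1 CD8 T cell marker, lower, and red cell and platelet markers, 1 higher and 3 lower, passed over the list alone as well. For CD8 T cell markers (median 0.05) camera pointed down, and for plasma cell markers (median -0.05) and mitochondrial transcripts up, against the sign of the median. B cell markers had 11 of 16 members higher (median 0.07), Ms4a1 for example at 7.90 ± 1.4 and 11.1 ± 3.5 CPM, and cytotoxic and NK cell markers 13 of 16 higher (median 0.20), although their more abundant members Nkg7 (24.1 ± 2.8 and 18.9 ± 4.4 CPM) and Prf1 (12.5 ± 3.0 and 10.0 ± 2.5 CPM) had negative fold changes. Red cell and platelet markers had 6 of 9 members lower (median -0.47), and Hbb-bs was the only one called over all genes with the block. Mitochondrial transcripts took 1.15 to 1.31% of CPM in every library, and the median log2 fold change of their list was -0.01.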

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

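Patz1, Gh and Gm33707 kept their direction and their call in every setting of the fit without the block that gave a value, with log2 fold changes of 1.28 to 1.36, 5.50 to 9.77 and 4.15 to 8.93, and 0 of the 16 key genes given was called in these. In the settings of the fit with the block 0 were called, except 1, Klrg1, with the Y-linked covariate. Gh and Gm33707 had no value without a library labelled MAZR-cKO where the filter was reapplied, since only 2 libraries then reached 1 CPM. DESeq2, the Y-linked covariate, the omission of X and Y genes, the scaling of lists, the same genes kept without single libraries or pairs, and all settings of the fit with the block were chosen after seeing the data. The count of 5 genes stayed within 1.5 times except for 9 with robust moderation, 33 with DESeq2, 46 with the replicate block, and, when leaving out single libraries, a range of 4 to 14 with the same genes kept and of 2 to 10 with the filter reapplied. The count of 46 with the block moved to 23 with quantile normalization, 25 with equal medians, 74 with robust moderation (48 higher, 26 lower), 30 with DESeq2, 13 at adjusted p under 0.01, 9 at an absolute log2 fold change over 1, and to a range of 8 to 279 without single pairs, or 5 to 311 with the filter reapplied. The 6 lists became 10 with the Y-linked covariate (4 higher), 0 with an estimated correlation, 0 with fry, 0 with the block and an estimated correlation, and 3 to 11 without single libraries. Stricter thresholds reduce the counts by construction, and for the other changes the cause was not tested.

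Some directions turned. With the Y-linked covariate the log2 fold change became 0.26 for Il2ra, 0.045 for Ctla4, 0.037 for Tnfrsf18, 0.048 for Ccr7, -0.077 for Zbtb7b and -0.017 for Runx1. Camera's adjusted p, with the direction now up, was 0.0295 for Treg core, 0.0011 for ribosomal proteins and 0.791 for MHC class I. Leaving out single libraries gave ranges across 0 of -0.28 to 0.037 for Il2ra, -0.072 to 0.051 for Ctla4 (0.050 without MAZR-cKO 1), -0.11 to 0.0054 for Ikzf2, -0.017 to 0.089 for Zbtb7b (-0.011 without MAZR-cKO 2), -0.095 to 0.015 for Cd44, -0.26 to 0.031 for Klrg1 (0.024 without WT 3) and -0.14 to 0.067 for Ccr7. For the cell cycle list the adjusted p ran from 8.2e-12 to 0.526, with the direction up without WT 1 (0.475, or 0.46 with the filter reapplied). The cause was not tested. Of the other named genes, 1312 results kept their direction and call, 53 calls were gained, mostly with the block or DESeq2, and 11 were lost, all of Cacna1g or Nod1, and no direction turned in the settings of the fit without the block. Apart from the gained genes, the 46 for 5, the 7 for 6 lists and the members passing over a list alone, the block changed no other call. Genes near 1 CPM rest on about 16 to 29 reads, so folds of such genes are limited by depth.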

Other observations

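The tests on Patz1, on Gh and Gm33707 and on the Treg core list were chosen after their results, or values that foretold them, were seen, and only those on other splits of the libraries were set before.

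The region around Gm33707 held the most abundant transcript that limma called with the block. Mbnl1, a regulator of alternative splicing on chromosome 3 from 60472830 to 60629750, ends 140 kb before Gm33707 and stood at 1435 ± 77 CPM in WT and 1834 ± 127 CPM in the libraries labelled MAZR-cKO (SD, n = 3, limma adjusted p = 0.032 with the block). Without the block, limma did not call Mbnl1 (adjusted p = 0.36), while DESeq2 did. With the block, Mbnl1 lost its limma call with no filter, quantile normalization, equal medians and the Y-linked covariate, and without replicate 1 or 2. Within the span of Mbnl1 the annotated model Gm37589 was at 1.18 ± 0.19 and 2.72 ± 1.2 CPM. Mbnl1 and Gm37589 are the only 2 other tested genes within 500 kb of Gm33707. Of 22 tested genes within 500 kb of Gh and 15 within 500 kb of Patz1, 0 were called with the block. Among the less changed genes called with the block were Ptprv at 86.0 ± 12 and 133 ± 21 CPM, Ly6c1, a surface protein of T cell subsets, at 31.9 ± 4.3 and 42.5 ± 6.7 CPM, and Crim1 at 76.4 ± 1.4 and 96.0 ± 3.6 CPM.

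Patz1 was 2.51-fold higher in the libraries labelled MAZR-cKO. An exchange of single libraries between the genotypes is argued against, since 0 libraries had Patz1 within the range of the other genotype. A complete exchange of the labels and a hypothesis in which loss of the protein raises a Patz1 transcript lacking the deleted part both allow the same ratio of 2.51, and they cannot be told apart in gene-level values without reads over the deleted exons. MAZR acting on its own gene may be one form of the latter, and it was not tested. The reads of Gh would speak against exchanged labels only if they came from the Cre line, which gene-level values do not show.

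Gh and Gm33707 were read almost only in the libraries labelled MAZR-cKO. Reads of Eno1 placed on its copy Gm33707 are argued against, because the ratio of Eno1 between the genotypes was 0.902 while that of Gm33707 was 488. Growth hormone sequences are common parts of transgenes, and a candidate explanation is an inserted transgene that carries such a sequence and lies near Gm33707. Both of the 2 other tested genes within 500 kb were higher at an unadjusted limma p under 0.05 with the block. The same held for 2 of 15 near Patz1, 2 of 22 near Gh and 3.98% of all tested genes. The 2 near Gm33707 overlap on the same strand, and their values had been seen before, so this decides nothing. A transgene cannot be told apart from a release of the endogenous Gh gene (46.8 CPM) after loss of MAZR, since the values do not show which part of Gh was read and the Cre line and the genotype coincide.

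Genes of the Treg core list were slightly lower in the libraries labelled MAZR-cKO. Fewer Treg cells among the sorted cells would lower Foxp3 as well, and it was not lower (log2 difference 0.05, SE 0.06). Foxp3 lay 2.99 of its standard errors above the median of the list. That distance leaves out the error of the list itself (SE 0.11 for the unpaired difference of its mean), so it does not decide the question. That SE also holds the spread between replicate numbers. Within the pairs, Foxp3 was higher under the MAZR-cKO label each time, at 1313, 1365 and 1415 CPM against 1252, 1345 and 1371 CPM in WT. These pairs speak against a fall of Foxp3, which is 1 gene, and no paired error was computed for its distance from the list. Scaling between libraries is argued against, since the median was -0.13 with quantile normalization and -0.13 with equal medians. The sex makeup of the libraries may contribute. Within WT and within the libraries labelled MAZR-cKO the mean of the list was higher where Y-linked transcripts were higher, by 0.18 and 0.15 on the log2 scale per 100 CPM. In fits without pairing, the difference of the mean went from -0.13 (SE 0.11) to 0.053 (SE 0.016) with the Y-linked sum as a covariate. Within each of the 3 pairs the mean was lower under the MAZR-cKO label, at 8.31, 8.12 and 8.42 against 8.39, 8.32 and 8.51 in WT. A part played by sex makeup cannot be told apart from an effect of genotype, as the Y-linked sum was lower in the library labelled MAZR-cKO of each pair. The slopes cannot be told apart from an effect of replicate number, as the Y-linked sum ran in the same order of replicate numbers under both labels. The covariate was also known to turn the list.

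The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. Without the block 1 of the 10, the real one, called as many as 5 genes, and the highest of the others was 0, also among the 3 others that part all pairs. With the block, only 4 splits part all 3 pairs, also too few, and 1 of them, the real one, gave as many as 46 genes, where the highest other gave 1. For the lists, all 10 splits called as many as the real 6, up to 18, and up to 9 among the splits that part all pairs. The split that calls 18, several times the real count, points to a structure among the libraries other than the genotype labels. It sets WT 1, WT 3 and MAZR-cKO 3, which had the highest Y-linked sums, against the rest. With the block the real split called 7 lists, and the others that part all pairs called 14, 8 and 12.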
